A study of Homo sapiens with 24 samples.

How the data were processed

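RNA was sequenced from formalin-fixed, paraffin-embedded skin biopsies of 12 patients with cutaneous T cell lymphoma (CTCL), each biopsied at baseline (cycle 1, day 1) and on treatment (cycle 2, day 15) with durvalumab, an antibody against PD-L1, and lenalidomide, a drug that binds cereblon. The 24 libraries fall into 2 groups of 12 by their labels, and the patient number in the labels joins the 2 libraries of a patient.

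The deposited values are raw counts of reads per gene, as whole numbers, in 1 table with 23354 gene rows. Per the submitters' processing notes, Trimmomatic, STAR 2.6.0, HTSeq 0.11.1 and edgeR were used. Those notes name the builds hg19 and hg38 without a role. Of 21956 gene symbols matched to a GRCh38 gene table, 0.237% had the same start, so the coordinates in the table are not those of GRCh38 and are given here as hg19. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes could be mixed. The table used here has 0 mitochondrial rows and 0 rows of immunoglobulin or T cell receptor segments. The planned shares of these genes were therefore not analysed here.

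Library totals ran from 7928890 to 17462592 counts at baseline and from 12909768 to 17923883 on treatment. Formalin-fixed RNA is fragmented, and reads without molecular identifiers are not independent molecules, so depth limits the precision of genes with few counts. The 89 rows of XIST, TSIX and the Y chromosome were removed before any fit.

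On-treatment libraries were compared with baseline libraries by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and the edgeR filter on low counts, which kept 15800 genes. The fit had no block. A second fit had the patient as a block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 50 in number, were tested with fry from limma 3.58.1, which asks whether the members move, on balance, one way. It keeps the correlation between genes and does not compare a list with other genes. Camera, an alternative, makes that comparison, so its p answers another question. The 46 lists with at least 3 tested members entered the test, adjusted over these lists. A list score is the mean log2 CPM (counts scaled to library size, prior count 2) of its tested members, and changes of scores are on-treatment minus baseline within a patient. Library measures were compared by two-sided permutation tests with 100000 resamples. Relations between score changes were tested over 12 patients by Pearson's r and Spearman's rho with 100000 permutations, adjusted over 5 relations.

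The tests, gene lists, alternatives and rule for named genes were set before the data were examined. Named genes are a fixed set of checkpoint, drug target, T cell and chemokine genes. To these were added the 10 genes that rose and the 10 that fell with the largest fold change among genes with adjusted p under 0.05, mean log2 CPM of 1 or more and the same direction in 9 or more of 12 patients. The 4 members with the smallest p under the block were added from each list that passed in either fit.

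The pairing was checked by correlating the deviations of the 2 libraries of a patient from their group means. The correlation was -0.079 at the lowest, 0.277 at the median and 0.619 at the highest, against a median of -0.015 between patients, and 10 of 12 pairs lay above 0.1. Of the 12 on-treatment libraries, 6 correlated best with the baseline library of their own patient. The labels give each pair as the same patient, and the pairing was used as labelled. No 2 libraries were identical.

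Alternatives were the patient block, DESeq2 1.42.0, limma-voom with and without quality weights, RLE and upper quartile normalization, other filters, a robust spread, camera, a keratinocyte covariate, medians, another prior count and leaving out each patient. No library had under 20% of the median total, so leaving out shallow libraries removed nobody. After the data had been seen, 4 alternatives were added: a correction of GC content and gene length trends between libraries, leaving out the 2 patients whose baseline libraries lay farthest from the rest, a T cell covariate, and separate fits in 2 sets of 6 patients by the GC trend of their libraries. Transcript GC content came from GENCODE transcripts, where 22414 of 23354 genes matched.

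The gene test was tested on simulated data with 200 changed genes, for the comparison of on-treatment with baseline libraries without the block. The filter kept 15656 genes, without some of the changed ones. Of the changed genes that were tested, it recovered 26% of those changed 1.5-fold, 65.3% of those changed 2-fold, 95.9% of those changed 4-fold and 97.9% of those changed 8-fold, with 7 false calls among 146. The list test recovered 10 of 10 simulated lists of 15 independent genes lowered 2-fold, with 0 false lists among the other 40. In both simulations all genes varied independently, with no patient effects and no far libraries. The rates may therefore not hold for the real libraries.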

Results

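Skin biopsies of 12 patients with relapsed or refractory CTCL, a lymphoma of T cells in the skin, were compared before and during treatment with durvalumab and lenalidomide. The libraries held 7928890 to 17462592 counts at baseline and 12909768 to 17923883 on treatment. Baseline libraries had 15678.6 ± 515.6 genes with 10 or more counts (mean ± SD, n = 12) and on-treatment libraries 15921.6 ± 266.5 (adjusted p = 0.249, two-sided permutation test). The 20 most abundant genes took 13.8% ± 2.04 of counts at baseline and 15.2% ± 2.88 on treatment (n = 12 each, adjusted p = 0.249). Total counts did not pass either (adjusted p = 0.249). These tests did not use the pairing. With sign flips of the changes within patients the adjusted p was 0.0868 for each of the 3 measures, and each was higher in 8 of 12 patients.

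The comparison asks what differed in the skin of these patients on treatment. The samples hold no untreated group and no group given either drug alone. The comparison therefore cannot separate treatment from time or the course of disease, or the drugs from each other. Genes of the cell cycle were lower on treatment and genes of blood vessel endothelium were higher. All 24 measured genes of the proliferation list had lower expression, with a median log2 fold change of -1.33, and 23 of them fell by the edgeR test (24 when adjusted over the list alone). With the patient as block 14 fell, and the median was -1.24. The list score fell by 1.27 ± 1.12 (SD, n = 12), and was lower in 10 of 12 patients (fry without the block, adjusted p = 0.0147, or 0.283 with an estimated correlation in camera). All 13 endothelial genes had higher expression, with a median log2 fold change of 0.72. Of these, 7 rose, 12 when adjusted over the list alone. The endothelial score rose by 0.77 ± 0.65 and was higher in 10 of 12 patients (fry without the block, adjusted p = 0.00208, or 0.181 with an estimated correlation in camera). With the patient as block, which uses the pairing, fry gave an adjusted p of 0.0294 for each of these 2 lists. Camera with an estimated correlation and the block gave 0.510 for each. Camera asks whether a list moved more than the other genes, which fry does not ask. Its higher p therefore does not mean that fry left out the correlation between genes. Without 2 patients whose baseline libraries lay far from the rest on principal components (distances 171.8 and 137.6 against a median of 43.6), the proliferation list no longer passed (adjusted p = 0.0754) and the endothelial list did (adjusted p = 0.00475). With the patient as block as well, neither passed (adjusted p = 0.0773 and 0.0574). The median log2 fold change in that fit was -0.99 for proliferation and 0.80 for endothelium, against -1.24 and 0.73 in the blocked fit of all patients. The farther of the 2 far baseline libraries had the lowest total (7928890 counts) and the fewest genes with 10 or more counts (14451). The other had 14989 such genes, with a total close to the baseline median of 13562400. Whether depth or RNA quality set these 2 libraries apart was not tested. A further baseline library, at a distance of 94.3, was kept, and the next farthest, an on-treatment library, lay at 66.9. The cut at 2 was thus a choice.

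Among cell cycle genes, MKI67, the gene of the Ki-67 proliferation antigen on hg19 chromosome 10 at 129894925 to 129924468, went from 348 ± 153 CPM to 140 ± 109 CPM (mean ± SD, n = 12 each). Its log2 fold change was -1.31 ± 0.34 (SE; edgeR adjusted p = 0.0377), and it was lower in 10 of 12 patients. The mitotic kinesin gene KIF11 on chromosome 10 at 94352825 to 94415152 fell by 1.22 ± 0.26 on the log2 scale (edgeR adjusted p = 0.0318), in 11 of 12 patients. The DNA replication helicase gene MCM4 fell by 0.86 ± 0.20. The spindle checkpoint gene BUB1B fell by 1.28 ± 0.33. The kinetochore gene SPC25 fell by 1.92 ± 0.45, the histone chaperone gene ASF1B fell by 2.12 ± 0.53, and both were lower in 11 of 12 patients. Without the 2 patients with far baseline libraries their log2 fold changes were -1.05 and -1.08, and neither passed (adjusted p = 0.101 and 0.132). ASF1B lost its call with the patient as block (-1.56 ± 0.43, adjusted p = 0.0545).

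Among endothelial genes, TEK, which encodes the angiopoietin receptor TIE2 on chromosome 9 at 27109147 to 27230172, rose from 12.5 ± 3.84 CPM to 24.5 ± 6.02 CPM in 12 of 12 patients. Its log2 fold change was 0.97 ± 0.17 (edgeR adjusted p = 0.0318). EMCN, the endomucin gene, rose by 0.97 ± 0.25 in 12 of 12 patients, and CDH5, the VE-cadherin gene, by 0.85 ± 0.17 in 11 of 12. PLVAP, a gene of fenestrated endothelium, had a log2 fold change of 0.73 ± 0.23 (adjusted p = 0.0698), which passed with the patient as block (adjusted p = 0.0423). With that block the smooth muscle and pericyte list also passed by fry (adjusted p = 0.0294, against 0.0706 without). Camera with an estimated correlation and the block, which compares a list with other genes, gave this list an adjusted p of 0.510. Its score was higher in 10 of 12 patients, by 1.20 ± 1.25. Of its 10 genes, 3 rose under the block and 0 without it, while adjusted over the list alone 9 rose under the block and 3 without it. The contractile genes ACTA2 (block log2 fold change 1.08 ± 0.23, adjusted p = 0.0423) and TAGLN (1.03 ± 0.23, adjusted p = 0.0428) and the pericyte gene RGS5 (1.00 ± 0.23, adjusted p = 0.0431) were the 3 that passed. LMOD1 had a block log2 fold change of 1.36 ± 0.39 (adjusted p = 0.0609).

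**Figure D1:**
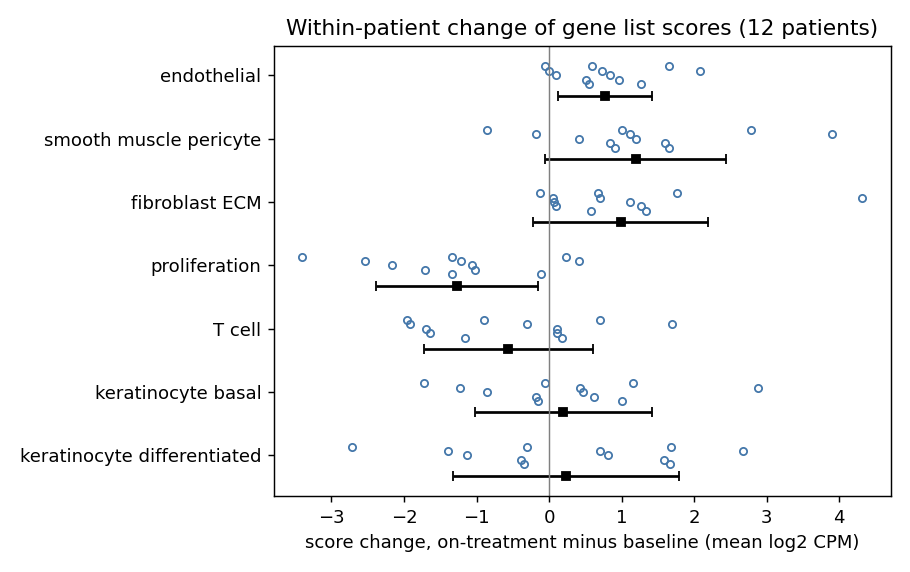
Change of gene list scores from baseline to on-treatment biopsy, in mean log2 CPM, for 7 lists. Circles are the 12 patients and squares with bars the mean ± SD. The endothelial and proliferation scores moved to opposite sides of 0 in 10 of 12 patients each, while the basal keratinocyte score was higher in 6 and lower in 6.

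The 10 genes with the largest rises had log2 fold changes from 1.34 to 2.06, and each also had a positive fold change with the patient as block. MMP11, which encodes the matrix metalloproteinase stromelysin-3 on chromosome 22 at 24115036 to 24126503, rose by 2.06 ± 0.55 on the log2 scale, from 3.45 ± 2.16 CPM to 14.5 ± 19.97 CPM (edgeR adjusted p = 0.0434; block 1.47 ± 0.41, adjusted p = 0.0555). COL8A1, a collagen VIII gene, rose by 1.60 ± 0.40 and the proteoglycan gene GPC4 by 1.60 ± 0.43, each in 11 of 12 patients. EDIL3, which encodes an integrin ligand, rose by 1.58 ± 0.36 and the tetraspanin gene TSPAN12 by 1.36 ± 0.34, each in 12 of 12 patients. HTRA1, a secreted protease gene, rose by 1.34 ± 0.33 in 11 of 12. MFAP2, a microfibril gene, rose by 1.43 ± 0.40 and GXYLT2 by 1.43 ± 0.40, and both lost their call under the block (1.25 ± 0.34 and 1.06 ± 0.41, adjusted p = 0.0538 and 0.128). PQLC2L (1.60 ± 0.39) and the pseudogene TPTE2P1 (1.42 ± 0.39) rose in 12 of 12 patients. Both have related copies, so reads could be split between them. The fibroblast and extracellular matrix list as a whole did not pass (fry adjusted p = 0.0706 without the block and 0.0666 with it). Without the block 0 of 18 genes were called, and 15 when adjusted over the list alone. With the block these counts were 1 and 16. Its score change was 0.99 ± 1.21, with higher values in 11 of 12 patients.

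The genes with the largest falls were unevenly expressed at baseline. The long noncoding RNA LINC00996 averaged 21.5 ± 67.1 CPM at baseline and 1.16 ± 0.98 CPM on treatment. Its log2 fold change was -4.20 ± 1.04 (edgeR adjusted p = 0.0361), but -1.13 ± 0.56 with the patient as block (adjusted p = 0.221). GNG4, a G protein subunit gene, fell by 3.87 ± 1.05 (block -2.00 ± 0.85, adjusted p = 0.161), the pseudogene CXCR2P1 fell by 2.70 ± 0.73 (block -1.64 ± 0.81, adjusted p = 0.224), and the zinc transporter gene TMEM163 fell by 2.68 ± 0.66 (block -1.64 ± 0.48, adjusted p = 0.0626). DPF3 fell by 2.18 ± 0.58, the histone gene HIST3H2BB fell by 2.09 ± 0.54 and the myosin gene MYO7A fell by 1.88 ± 0.52. Their block log2 fold changes were -1.17 ± 0.37, -1.72 ± 0.47 and -1.20 ± 0.45 (adjusted p = 0.0799, 0.0526 and 0.120). Reads of CXCR2P1 and HIST3H2BB could be shared with related genes. The median log2 fold change of the 10 genes with the largest falls went from -2.31 to -1.44 without the 2 patients with far baseline libraries, and that of the 10 largest rises from 1.51 to 1.52. Under the block 1 of the 10 genes with the largest falls passed, SPC25, against 7 of the 10 with the largest rises.

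Of genes associated with malignant T cells in CTCL, GTSF1 fell by 2.44 ± 0.56 (edgeR adjusted p = 0.0318; block -2.13 ± 0.59, adjusted p = 0.0549) and was lower in 10 of 12 patients. TOX, a T cell transcription factor gene on chromosome 8 at 59717977 to 60031767, went from 94.2 ± 131 CPM to 24.7 ± 11.1 CPM. Its log2 fold change was -1.93 ± 0.49 (adjusted p = 0.0369), but -1.13 ± 0.46 under the block (adjusted p = 0.151), and it was lower in 7 of 12 patients. The list of CTCL-associated genes did not pass (adjusted p = 0.619; 2 of 8 members fell), with a median log2 fold change of -0.40. With the patient as block the median was -0.01 and 0 members passed (list adjusted p = 0.937), and the score was higher in 7 of 12 patients. The T cell list had 0 of 15 genes called, or 8 lower without and 0 with the block when adjusted over the list alone. Its median log2 fold change was -1.02, or -0.58 under the block, and its score change -0.56 ± 1.16 (fry adjusted p = 0.231 without the block and 0.247 with it). Its score was lower in 7 of 12 patients.

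**Figure D2:**
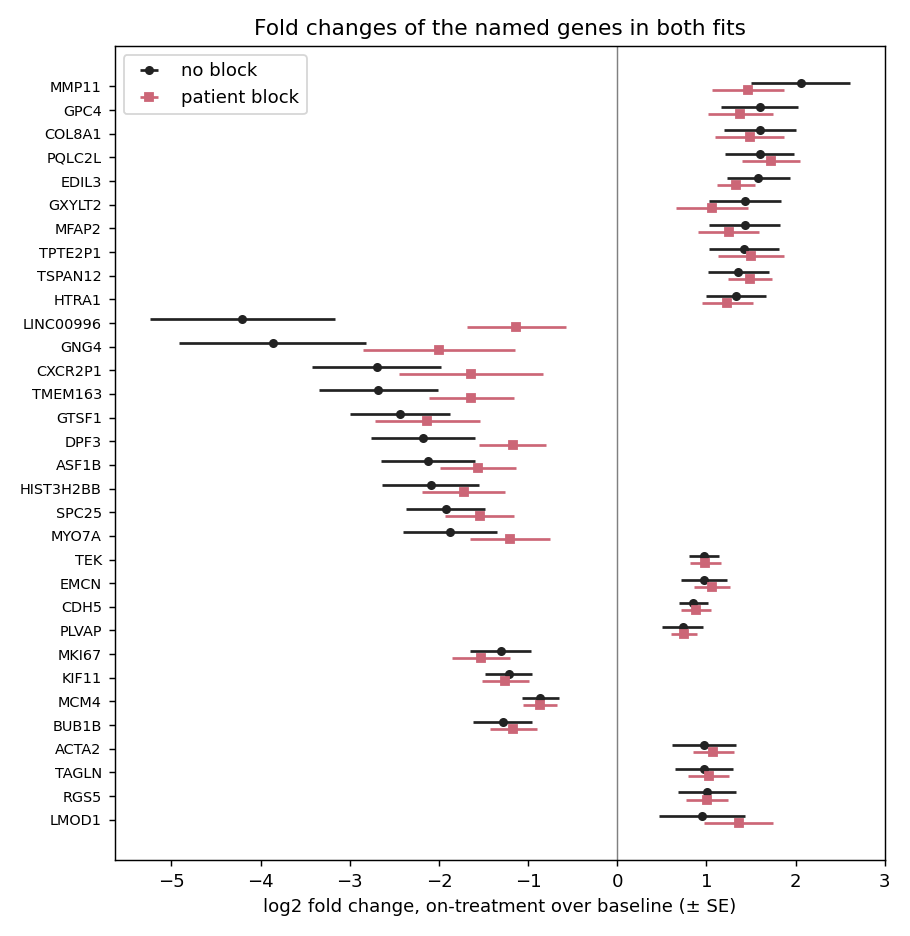
Log2 fold changes (on-treatment over baseline, ± SE) of the named genes chosen by size or list membership, without a block (circles) and with the patient as block (squares). LINC00996 moved from -4.20 to -1.13 under the block, while TEK was 0.97 and 0.99.

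The treatment's target genes did not pass the edgeR test, although CD274 and PDCD1 passed by DESeq2 (adjusted p = 0.0369 and 0.0160). CD274, which encodes PD-L1, had 34.3 ± 15.5 CPM at baseline and 19.7 ± 8.35 CPM on treatment, with a log2 fold change of -0.80 ± 0.26 (edgeR adjusted p = 0.0771), and was lower in 10 of 12 patients. PDCD1, the gene of its receptor PD-1, had a log2 fold change of -1.48 ± 0.45 (adjusted p = 0.0625; block -0.97 ± 0.35, adjusted p = 0.111), also lower in 10 of 12. CRBN, the gene of cereblon, had a log2 fold change of 0.17 ± 0.11 (adjusted p = 0.397). Transcripts of IKZF1 and IKZF3, whose proteins are degraded in the presence of lenalidomide, had log2 fold changes of -0.25 ± 0.23 and -0.04 ± 0.30 (adjusted p = 0.571 and 0.960). IRF4 was at -0.18 ± 0.35 (adjusted p = 0.810). Of the other checkpoint genes, TIGIT was at -1.08 ± 0.46 (adjusted p = 0.170; block -0.44 ± 0.42), PDCD1LG2 at -0.28 ± 0.22, CTLA4 at -0.26 ± 0.39, ICOS at -0.24 ± 0.46, HAVCR2 at -0.07 ± 0.31 and LAG3 at 0.20 ± 0.42. The adjusted p of the last 5 ran from 0.487 for PDCD1LG2 to 0.924 for HAVCR2.

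CD8A, a marker of cytotoxic T cells, had 18.3 ± 17.1 CPM at baseline and 39.0 ± 41.03 CPM on treatment, and was higher in 11 of 12 patients. Its log2 fold change was 1.09 ± 0.57 (edgeR adjusted p = 0.272), or 1.30 ± 0.39 with the patient as block (adjusted p = 0.0658). The cytotoxic list did not pass (adjusted p = 0.604). The median log2 fold change of its genes was -0.38 without the block and 0.58 with it (block adjusted p = 0.177). Without the block it was also positive without the 2 patients with far baseline libraries (0.76), by DESeq2 (0.16) and by limma-voom (0.46). It stayed negative without the block under RLE (-0.37) and upper quartile (-0.33) normalization and with GC and length offsets (-0.25). By limma-voom with the block it was -0.05, so its sign depended on the setting. Adjusted over the list alone, 0 genes were higher without the block and 5 with it. Its score change was 0.47 ± 1.25, with higher values in 10 of 12 patients. GZMB was at -1.53 ± 0.82 (adjusted p = 0.281; block -0.50 ± 0.62) and the regulatory T cell gene FOXP3 at 0.05 ± 0.54 (adjusted p = 0.970). The interferon-induced chemokine genes CXCL9 and CXCL10 were at -1.25 ± 0.67 and -1.01 ± 0.68 (adjusted p = 0.278 and 0.400).

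Across all genes, 492 of 15800 passed, 251 higher and 241 lower, with a smallest adjusted p of 0.0318. With the patient as block 617 passed, 359 higher and 258 lower, and 333 genes passed both fits in the same direction. Without any 1 of 7 patients the fit without block called 0 genes, as did the blocked fit for 8 of the 12, and without the 2 patients with far baseline libraries both fits called 0. In those 2 fits edgeR gave 3085 and 4194 genes at an unadjusted p under 0.05, while for all patients limma-voom called 287 genes and DESeq2 1322. Random regrouping of the libraries of all patients gave up to 3158 genes at that p without the block. Swaps of libraries within patients gave up to 2615 with the block. No regrouping was run without the 2 patients.

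Changes of 5 pairs of measures were compared across the 12 patients. T cell and CTCL-associated scores changed together (r = 0.76, permutation p = 0.00506, adjusted p = 0.0253; rho = 0.78, p = 0.00448, adjusted p = 0.0224). These scores are not separate measures, because the CTCL-associated list holds genes linked to malignant T cells, such as TOX and GTSF1. Without the 2 patients farthest out on the T cell axis r was 0.76 (p = 0.0159, adjusted p = 0.0793). Within 2 sets of 6 patients separated by the GC trend of their libraries, r was 0.47 and 0.80 (exact permutation p = 0.353 and 0.0931), so the relation did not pass within either set. CD274 and the interferon gamma response score had r = 0.53 (p = 0.0738, adjusted p = 0.123) and rho = 0.71 (p = 0.0126, adjusted p = 0.0314). Without the 2 patients farthest out on CD274 r was 0.45 (p = 0.196), and within the 2 sets it was 0.47 and 0.84 (exact permutation p = 0.357 and 0.0417). Cytotoxic and interferon gamma response scores had r = 0.69 (p = 0.0241, adjusted p = 0.0603) and rho = 0.43 (p = 0.162), with r = 0.56 without 2 patients and 0.71 and 0.64 within sets. B cell and T cell scores had r = 0.36 (p = 0.243) and rho = 0.43 (p = 0.161), with r = 0.60 without 2 patients and -0.52 and 0.31 within sets. T cell and differentiated keratinocyte scores had r = -0.09 (p = 0.789) and rho = -0.23 (p = 0.469), with r = -0.31 without 2 patients and -0.21 and 0.19 within sets.

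**Figure D3:**
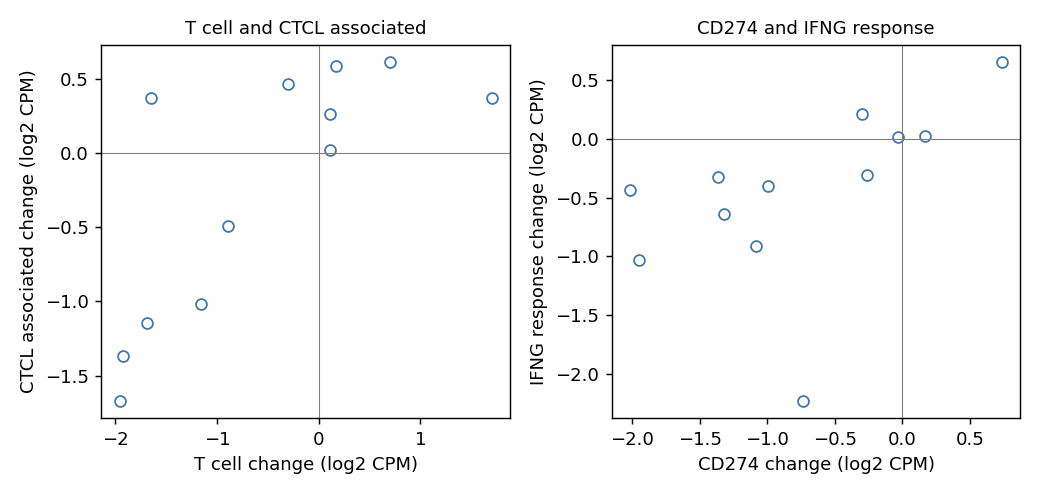
Within-patient changes in log2 CPM of the T cell and CTCL-associated scores (left, r = 0.76) and of CD274 and the interferon gamma response score (right, r = 0.53). Circles are the 12 patients. On the right 1 patient lies far below the others in the interferon gamma response score.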

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

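The count of changed genes was not stable. With all patients the smallest adjusted p was 0.0318 without and 0.0423 with the patient as block, both close to the threshold. Without a block, edgeR called 492 genes, against 286 with no filter on low counts, 287 by limma-voom, 830 by limma-voom with quality weights and 1322 by DESeq2. With the patient as block it called 617, against 940 by limma-voom and 2443 by DESeq2 with the same block. Leaving out each patient gave 0 to 686 genes without and 0 to 1190 with the block. It gave 1 to 4 gene lists without and 0 to 5 with the block, where 2 and 3 passed with all patients. The endothelial list passed in 12 of these 12 fits without the block and 5 of 12 with it, the proliferation list in 10 and 5, and the smooth muscle and pericyte list in 1 and 4. The patients are not named here.

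With settings chosen after the data were seen, 0 genes passed without the 2 patients with far baseline libraries (1 list without and 0 with the block), 0 genes and 0 lists with a T cell covariate and the block, and 0 genes in either set of 6 patients (0 lists in the set with the lower GC trend and 4 in the other, smallest adjusted p 0.0498: 2 higher, and the IL6 and STAT3 and the TNF and NF-kB lists lower). Unadjusted p lay under 0.05 for 3354 genes with the T cell covariate and for 2898 and 2120 genes in the 2 sets. With GC and length offsets and block, 422 genes and 5 lists passed. Camera passed 0 lists with an estimated correlation, 18 with a preset correlation, and 0 and 19 with the block. With the T cell covariate the list medians went from -1.24 to -1.13 (proliferation), 0.73 to 0.59 (endothelial) and 1.15 to 1.05 (smooth muscle). The cause of these changes was not tested, apart from the fewer libraries in some fits. The patient block changed no call of a library measure.

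Among the named genes and library measures, the values that changed sign between settings came from comparisons that did not pass. These were the share of the 20 most abundant genes (-0.199 percentage points by medians), HAVCR2 (0.0012 under the block, 0.27 without the 2 patients), ICOS (0.12 by limma-voom), IKZF3 (0.15 without the 2), FOXP3 (-0.22 without the 2) and GZMB (0.15 by DESeq2, 0.18 without the 2). Of the 492 genes called without the block, 491 kept their sign under it. Among list medians, the block changed the sign of the cytotoxic list (-0.38 to 0.58) and of basal keratinocyte genes (-0.07 to 0.15). It also changed that of differentiated keratinocyte genes (-0.12 to 0.23) and B cell genes (-0.03 to 0.42). Glucocorticoid-induced genes (-0.15 to 0.06) and p53 targets (-0.06 to 0.01) changed sign as well. None of these lists passed in either fit. The T cell list was at -0.58 under the block, at 0.10 in the set with the higher GC trend and at -1.18 in the other (adjusted p = 0.0872). The relation of cytotoxic and interferon gamma response scores passed with a prior count of 0.5 (r = 0.70, adjusted p = 0.0464), and that of T cell and CTCL-associated scores was lost without 2 patients (r = 0.76, adjusted p = 0.0793). RLE and upper quartile normalization kept every count of genes and lists within 1.5 times.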

Other observations

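The tests of GC content, the 2 sets of 6 patients by GC trend, T cell share, dermis share and the far libraries for gene lists were chosen after the results were seen. The splits of the libraries and the removal of other pairs of patients were chosen before their results were seen.

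Immune signaling and antigen presentation lists lay lower on treatment without passing by fry, with or without the block. MHC class I genes had lower expression for 12 of 12 members and a score change of -0.41 ± 0.46, lower in 11 of 12 patients. Their adjusted p was 0.11 without the block and 0.0666 with it, where 2 members were called lower. The IL2 and STAT5 list was also lower in 11 of 12 patients (score change -0.48 ± 0.54, adjusted p = 0.188, block 0.105). The dendritic and Langerhans cell list was lower in 10 of 12 (-0.52 ± 0.77, adjusted p = 0.167, block 0.0988). The IL6 and STAT3 list (-0.43 ± 0.55, adjusted p = 0.101, block 0.0657) and the TNF and NF-kB list (-0.48 ± 0.93, adjusted p = 0.101, block 0.105) were lower in 10 and 9 of 12. In the 6 patients with the higher GC trend these 2 lists passed under the block (adjusted p = 0.0498 each, median log2 fold changes -0.69 and -0.99), while in the other 6 the medians were -0.22 and -0.19, without passing. Lymphatic endothelial genes were higher in 10 of 12 patients (0.84 ± 0.90, fry adjusted p = 0.0701 without the block and 0.0657 with it). Mast cell genes were higher in 9 of 12 (0.69 ± 1.02, adjusted p = 0.101, block 0.105), as were adipocyte genes (1.71 ± 2.38, adjusted p = 0.167, block 0.105).

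Whether chance can account for the counts was tested by regrouping the 24 libraries. Of 100 splits drawn without regard to patients, 1, the real one, gave 492 or more genes, and the highest of the others gave 232. Of 100 splits that swap the 2 libraries within patients, 1, the real one, gave as many genes in either fit, 492 without the block and 617 with it, and the highest other gave 0 in both. For gene lists, 3 of the 100 random splits gave 2 or more (highest other 2). Of the 100 swaps, 1 gave 2 or more lists without the block (highest other 1) and 2 gave 3 or more with the block (highest other 4). With 100 splits the smallest possible share is 1 of 100, so they argue against chance for the counts of genes without excluding it. This does not make these counts stable. The real grouping also gave the most genes at an unadjusted p under 0.05 (edgeR). Without the block it gave 3385, against up to 3158 in the other random splits and up to 2420 in the other swaps. With the block it gave 3934, against up to 2615 in the other swaps. For lists the shares were under 0.05, but other splits gave as many lists or more, except for the swaps without the block.

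The lower cell cycle genes were weighed against 3 explanations, of which a lower share of T cells is not a technical one. A GC or length trend between libraries is argued against, because the list passed with the offsets and the block (adjusted p = 0.0225) and its median log2 fold change was -1.24 before and after. The 2 far baseline libraries alone are argued against, because the score change was -1.01 ± 0.96 in the other 10 patients and negative in 8 of them (sign-flip permutation p = 0.0132), although the median fold change went from -1.33 to -0.89 and the list lost its call. A lower share of T cells may contribute: the proliferation score minus the T cell score changed by -0.706 ± 1.496 (sign-flip p = 0.0579), which does not separate them. In the 6 patients with the higher GC trend the T cell median was 0.10 and the proliferation median -1.30 (block, adjusted p = 0.182), against -1.18 and -1.24 in the other 6. That goes against fewer T cells as the whole cause, but with proliferation not passing in either set it does not decide. With the T cell covariate the median log2 fold change was -1.13 against -1.24, and the list lost its call (adjusted p = 0.144) for a reason that was not tested.

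The higher endothelial genes were weighed in the same way. A GC or length trend is argued against (adjusted p = 0.0225 with the offsets and block; median log2 fold change 0.73 before and 0.83 after), as are the far libraries (score change 0.79 ± 0.65 in the other 10 patients, positive in 9 of them, sign-flip permutation p = 0.00367). Fewer T cells would raise other cell types alike, and the endothelial score changed by 0.57 ± 1.48 more than the basal keratinocyte score (sign-flip p = 0.210), which leaves this open. With the T cell covariate the median log2 fold change was 0.59 (quartiles 0.50 and 0.73) against 0.73 (quartiles 0.71 and 0.85), and the list lost its call (adjusted p = 0.144) for a reason that was not tested. A larger share of dermis in the on-treatment biopsies could also raise them. The basal keratinocyte score, which it would lower, changed by 0.20 ± 1.22 (sign-flip p = 0.602). Its median log2 fold change under the block was 0.15 in all patients and -0.23 without the 2 patients with far baseline libraries. The lists of fibroblasts and matrix, smooth muscle, lymphatic endothelium, adipocytes and Schwann cells were higher in 9 to 11 of 12 patients, as a larger share of dermis would need. Those of sweat glands, sebaceous glands and hair follicles were higher in 8, 7 and 7 of 12. With the differentiated keratinocyte score as covariate and the block, the endothelial median log2 fold change was 0.73 and the list passed (fry, adjusted p = 0.048). A larger share of dermis stays open too. A response of vessels to treatment was not tested apart from these.

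The falls of single genes may rest in part on the 2 far baseline libraries. Leaving out those 2 patients took the median within-patient change of the 241 genes that fell from -1.05 to -0.86, a larger loss than for 98.5% of the other pairs of patients. For the 251 genes that rose it went from 0.82 to 0.78, a larger loss than for 70.8% of other pairs. GC or length trends may also contribute to single gene calls. Log2 fold changes had a Spearman rho of -0.19 with GC content and 0.17 with length (-0.17 and 0.16 with the block). Median GC content and length were 44.5% and 5.24 kb for genes that rose. They were 49.99% and 3.44 kb for genes that fell, against 48.2% and 3.52 kb for all tested genes. With the offsets 657 genes passed, including 420 of the 492. With the block as well 422 passed, including 368 of the 617.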
